A study of Homo sapiens with 12 samples.

How the data were processed

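RNA-seq of poly-A selected mRNA was analysed for 12 samples of HIBEpiC, a human intrahepatic biliary epithelial cell line, in 4 groups of 3 libraries. The submitters described the cell experiments as done in triplicate. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The strand setting of the libraries and of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

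The deposited values are FPKM (fragments per kilobase of gene and per M reads, M standing for 1e6), 1 value per gene and sample, for 58735 Ensembl gene IDs. All 58735 IDs are in GENCODE release 29 on the human build GRCh38, and 58207 were matched to a symbol in the name table. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with no role given for any of them. The same notes name the mouse build mm10, which contradicts the human IDs. Coordinates given here are those of GENCODE 29 on GRCh38, 1-based.

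Multiplying each deposited FPKM value by the exon-union length of its gene gave whole reads at 1 common step per library. Within a tolerance of 0.05 reads, 100% of the values were whole, with a largest deviation of 5.9e-05. The recovered depth was 15.3 to 20.8 M reads in genes per library. The library totals inside the deposited FPKM were proportional to median-of-ratios size factors, so the authors' values already carry that scaling, and 25555 genes had no read in any library. Over the 12 pairs of replicates, chi-square per degree of freedom on the recovered reads was 2.5 to 4.7 in genes with at least 20 reads per pair. No pair of replicates therefore differed by as little as sampling noise, and all 12 libraries were kept as separate samples.

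The plan fixed before the data were examined assumed count tables. Because the values are FPKM, the tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, the fallback of the same plan. All 12 libraries entered 1 linear model with 8 residual degrees of freedom, with an empirical Bayes variance trend and a two-sided moderated test. Genes needed at least 0.5 FPKM in at least 3 libraries, which left 14870 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. A log2 change here is on the log2(FPKM + 1) scale, which understates the change of genes near or below 1 FPKM; a fold is the ratio of the mean FPKM of 2 groups. Values are given as mean ± SD over 3 libraries.

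The 4 comparisons were TGF-β against vehicle, each compound with TGF-β against TGF-β alone, and the compounds against each other. The groups, the tests, 37 gene lists and the rule for named genes were chosen before the data were examined. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 144 tests of 36 lists in 4 comparisons. Each test was repeated with an estimated correlation, and counts of members were also adjusted over the list alone. Named genes were the 10 highest and 10 lowest called genes of a comparison with mean log2 CPM of at least 3 and no overlap between the groups, up to 4 members of each list with the smallest adjusted p, and a fixed set of genes of the TGF-β, cyclooxygenase, epithelial, proliferation and stress responses. A gene named in 1 comparison may be given in another. MT-RNR1, MT-RNR2, MT-CO1, the genes changed in opposite directions and the gene families were chosen after their values were seen. No level of XIST or of a Y-linked gene is reported, and some genes named by the rule are not reported here.

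The tests were checked on simulated libraries with up to 50 genes changed at each of 4 known folds, drawn from the means, depths and spread of the real ones. For TGF-β against vehicle, with 15059 simulated genes tested, 34% of genes changed 1.25-fold were called, 64% at 1.5-fold, 77.6% at 2-fold and 96% at 4-fold, and 4.7% of calls were false. For celecoxib against TGF-β alone, with 15065 genes, these shares were 24%, 72%, 83.7% and 100%, with 7.7% false. For the analog against TGF-β alone, with 15076 genes, they were 36.7%, 70.2%, 90% and 98%, with 9.9% false. Between the compounds, with 14643 genes, they were 34.7%, 74%, 90% and 100%, with 3.9% false. Far fewer genes changed in these simulations than were called in the real comparisons. The shares called and false therefore need not hold for the real calls. The estimated change was 0.71 to 0.88 of the true one. A first criterion of 90% recovery at folds of at least 2 over all genes was not met, and was then restricted to genes at or above 5 FPKM, where recovery was 100% and the ratio 0.91 to 0.95. A list with a built-in change was called in each simulated comparison. All its genes rose by the same fold and were drawn independently, so this call is no check on correlation between genes.

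Alternatives chosen in advance were another filter on low values and none, limma-voom on the recovered reads, stricter thresholds, a fit of the 2 groups compared, the replicate number as a block, leaving out each library and, for the lists, an estimated correlation and the fry test. Alternatives added after seeing the data were TMM scaling, total read scaling, pseudocounts of 0.1 and 5, and removal of the trend with GC content. Figures and summaries were made with Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.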

Results

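HIBEpiC cells were treated in 4 ways to ask how celecoxib, an inhibitor of cyclooxygenase-2 (COX-2), acts on proliferation and fibrosis-related genes in biliary epithelium, and whether the action needs COX-2 inhibition. The vehicle group was kept for 28 h in medium with 0.1% DMSO and 0.5% bovine serum albumin. The TGF-β group received 20 ng/mL of TGF-β, a cytokine that drives matrix production, for 24 h after 4 h without it. The other 2 groups received 10 µM celecoxib or 10 µM 2,5-dimethyl-celecoxib for the first 4 h and then TGF-β for 24 h with the compound. 2,5-dimethyl-celecoxib, called the analog here, is a close structural relative of celecoxib that lacks COX-2 inhibition. Each group held 3 libraries with 15.3 to 20.8 M reads in genes.

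The libraries separated by treatment. The first principal component held 57% of the variance and the second 18.1%. Correlations of log2 values were at least 0.9886 within groups and at most 0.9864 between groups.

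**Figure D1:**
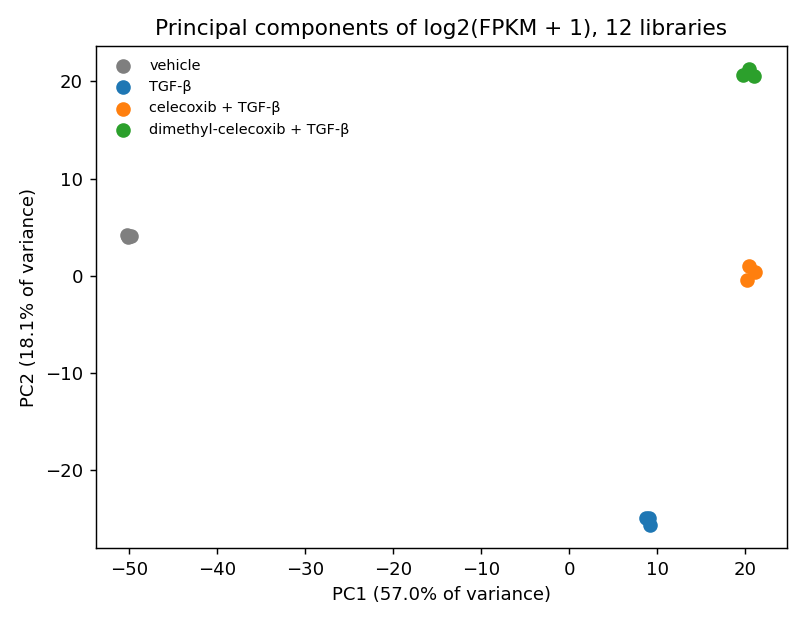
Each point is 1 of 12 libraries on the first 2 principal components of log2(FPKM + 1), coloured by group, with the percent of variance on each axis. The first component holds 57% of the variance and the second 18.1%, and the 3 libraries of each group lie together.

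PTGS2, the gene of COX-2, gave 4 reads over all 12 libraries, all of them in the TGF-β group. PTGS1, the gene of COX-1, gave 239 reads in the vehicle group, 13 with TGF-β, 16 with celecoxib and 24 with the analog. Both lay below the expression floor and were not tested. CDH1, the gene of the epithelial adhesion protein E-cadherin, was below the floor too, with 129, 145, 97 and 112 reads in the same order. CYP1A1, a target of the aryl hydrocarbon receptor, gave 7 reads with vehicle, 2 with TGF-β and 0 with either compound, which is too few for a statement on its direction.

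TGF-β against vehicle gives the response to the cytokine alone. Genes of the extracellular matrix and of the TGF-β pathway were among those that rose. COL1A1, which encodes a chain of type I collagen, rose 31.6-fold, from 3.81 ± 0.259 to 120.5 ± 5.46 FPKM (SD, n = 3; log2 change 4.66, SE 0.06, limma adjusted p = 1.7e-13). FN1, the gene of fibronectin, rose 8.08-fold, from 58.8 ± 2.08 to 475 ± 25.9 FPKM, and CCN2, a matricellular growth factor induced by TGF-β, rose 20.8-fold to 147 ± 10.1 FPKM. In the other direction, AQP3, a water channel, fell from 55.9 ± 3.07 to 1.83 ± 0.225 FPKM, and AREG, a ligand of the EGF receptor, fell from 20.3 ± 0.869 to 0.863 ± 0.14 FPKM.

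COL1A1 (ENSG00000108821) lies on chromosome 17 at 50183289 to 50201632, FN1 (ENSG00000115414) on chromosome 2 at 215360440 to 215436172, and CCN2 (ENSG00000118523) on chromosome 6 at 131948176 to 131951373. AREG (ENSG00000109321) lies on chromosome 4 at 74445134 to 74455009.

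In all, 3880 genes rose and 3919 fell with TGF-β among 14870 tested (52.4%), and 588 of the first and 314 of the second changed by at least 1 on the log2 scale. Scaling by total reads would shift the median change of all genes from -0.005 to -0.112 and the share of called genes that rose from 49.7% to 32.8%, so changes are relative to the typical gene. The median standard error of a log2 change was 0.07.

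Of the 21 tested immediate targets of TGF-β signalling, 17 rose and 2 fell, and adjusted over the list alone the counts were also 17 and 2 (camera adjusted p = 4.5e-09; adjusted p = 0.004 with an estimated correlation). SMAD7, an inhibitor of the pathway, rose 7.51-fold, and PMEPA1, another feedback inhibitor, rose 7.30-fold to 326 ± 2.75 FPKM. Receptors and SMAD proteins were not called as a list (9 rose and 4 fell of 15, adjusted p = 0.091). TGFB1 rose 2.37-fold and SMAD3, a signal transducer of the receptor, fell to 0.651 of its vehicle level. The BMP-responsive ID genes were not called either (0 rose and 2 fell of 3, adjusted p = 0.094). ID1, an inhibitor of differentiation factors, fell from 288 ± 12.5 to 23.4 ± 2.14 FPKM, and ID3 did not pass the test at 33.6 ± 2.24 and 35.4 ± 0.488 FPKM.

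All 3 matrix lists were higher, and none of the 3 calls held with an estimated correlation. Among collagens 13 rose and 5 fell of 18 (adjusted over the list alone 13 and 5; adjusted p = 0.0018, and adjusted p = 0.28 with an estimated correlation). COL4A1, a basement membrane collagen, rose 5.93-fold, and COL3A1, a fibrillar collagen, fell to 0.328 of its vehicle level. COL1A2, also a gene of type I collagen, lay below the expression floor, with no group mean above 0.204 FPKM, and was not tested. Among matrix glycoproteins and proteoglycans 15 rose and 4 fell of 22 (16 and 4 adjusted over the list alone; adjusted p = 5.8e-06, and adjusted p = 0.2 with an estimated correlation). SPOCK1, a secreted proteoglycan, rose 5.63-fold, from 16 ± 0.639 to 90.3 ± 3.63 FPKM. Among matrix remodelling enzymes 21 rose and 2 fell of 30 (21 and 2 adjusted over the list alone; adjusted p = 1.4e-07, and adjusted p = 0.091 with an estimated correlation). LOX, a collagen cross-linking enzyme, rose 15.8-fold, and ADAM19, a membrane metalloprotease, rose 15.3-fold.

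Contractile and actin cytoskeleton genes rose, 17 up and 2 down of 22 (17 and 2 adjusted over the list alone; adjusted p = 8.4e-08; adjusted p = 0.017 with an estimated correlation). TAGLN, which encodes the smooth muscle protein transgelin, rose 12.7-fold to 10.4 ± 0.661 FPKM, and TPM1, a tropomyosin, rose 4.45-fold. ACTA2, the gene of smooth muscle actin and a myofibroblast marker, was at 1.68 ± 0.13 and 1.61 ± 0.191 FPKM and did not pass the test (log2 change -0.04, 95% interval -0.30 to 0.22). Mesenchymal transition genes also rose, 8 up and 2 down of 10 (8 and 2 adjusted over the list alone; adjusted p = 0.00022; adjusted p = 0.024 with an estimated correlation). VIM, the gene of vimentin, rose 2.17-fold and CDH2, the gene of N-cadherin, rose 2.33-fold.

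Epithelial genes moved in both directions. Of 22 tested junction genes, 9 rose and 12 fell (adjusted p = 0.41). TJP3, a tight junction scaffold, fell from 10.1 ± 0.58 to 0.268 ± 0.117 FPKM, EPCAM fell to 0.572 of its vehicle level, and TJP1 and DSP rose 2.22-fold and 2.43-fold. Of 15 cholangiocyte markers, 6 rose and 6 fell (adjusted p = 0.95; 5 and 8 under total read scaling). The keratin gene KRT7 rose 1.87-fold to 1569 ± 39.1 FPKM, KRT19 did not pass the test at 1249 ± 5.08 and 1163 ± 57.9 FPKM but was lower with limma-voom (adjusted p = 0.0283) and total read scaling (adjusted p = 0.000552), and MUC1 fell to 0.228 of its vehicle level. Integrins were called higher, 8 up and 5 down of 13 (8 and 5 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation), with ITGB3 up 10.8-fold and ITGA5 up 4.67-fold.

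Proliferation genes fell. In the DNA replication and G1/S list 44 of 50 fell and 0 rose (45 and 0 adjusted over the list alone; adjusted p = 2.3e-11; adjusted p = 0.0015 with an estimated correlation). PCNA, the replication clamp, fell from 128 ± 1.87 to 90.7 ± 2.56 FPKM, and E2F1, a transcription factor of S-phase entry, fell from 40.8 ± 1.43 to 31.6 ± 0.831 FPKM. In the mitosis and G2/M list 53 of 60 fell and 0 rose (53 and 0 adjusted over the list alone; adjusted p = 1.3e-12, and adjusted p = 0.061 with an estimated correlation). AURKA, a mitotic kinase, fell from 30.4 ± 0.687 to 19.8 ± 0.545 FPKM, and the proliferation marker MKI67 fell from 9.61 ± 0.396 to 7.12 ± 0.82 FPKM. Neither CDK inhibitors and D cyclins (6 rose and 4 fell of 13, adjusted p = 0.51) nor p53 targets (10 rose and 7 fell of 27, adjusted p = 0.43, and 7 and 9 under total read scaling) were called. CDKN1A, the gene of the cell cycle inhibitor p21, rose 2.11-fold, as did CCND1, the gene of cyclin D1, by 2.28-fold.

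ER chaperones and unfolded protein response genes were higher, 24 up and 3 down of 34 (25 and 3 adjusted over the list alone; adjusted p = 8.9e-05, and adjusted p = 0.12 with an estimated correlation), with the chaperone gene HSPA5 up 1.36-fold. Cholesterol synthesis and uptake was called higher, 19 up and 6 down of 26 (19 and 6 adjusted over the list alone; adjusted p = 0.0055, and adjusted p = 0.33 with an estimated correlation). SQLE, a sterol synthesis enzyme, rose 1.62-fold. NRF2 targets were lower, 5 up and 24 down of 34 (6 and 24 adjusted over the list alone; adjusted p = 9.6e-06, and adjusted p = 0.12 with an estimated correlation). AKR1B10, an aldo-keto reductase, fell from 27.8 ± 1.63 to 0.59 ± 0.313 FPKM, and TXNRD1, thioredoxin reductase, fell to 0.345 of its vehicle level. Lysosome and autophagy genes were called higher, 19 up and 8 down of 35 (19 and 9 adjusted over the list alone; adjusted p = 0.018), with adjusted p = 0.22 with an estimated correlation and adjusted p = 0.078 under total read scaling, where 13 rose and 12 fell. ULK1, an autophagy kinase, rose 6.92-fold.

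Interferon-stimulated genes fell, 3 up and 18 down of 30 (4 and 18 adjusted over the list alone; adjusted p = 0.00026; adjusted p = 0.019 with an estimated correlation). IFIT2 fell from 13.8 ± 1.28 to 1.68 ± 0.26 FPKM and the transcription factor gene IRF1 to 0.379 of its vehicle level. NF-kB and inflammatory cytokine genes were not called (16 rose and 14 fell of 33, adjusted p = 0.8, and 14 and 14 under total read scaling): IL11, a profibrotic cytokine, rose 14.6-fold and CXCL8, a neutrophil attractant, fell to 0.141 of its vehicle level.

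The other lists were not called for TGF-β. The tested members that rose and fell were 3 and 7 of 13 for the prostanoid pathway, 18 and 12 of 42 for ATF4 targets, 8 and 4 of 19 for fatty acid synthesis (7 and 7 under total read scaling), 3 and 9 of 17 for PPAR targets and 1 and 3 of 5 for aryl hydrocarbon receptor targets. They were 9 and 14 of 33 for the BCL2 family, 6 and 13 of 24 for heat shock, 14 and 9 of 34 for hypoxia and glycolysis (12 and 15 under total read scaling), and 0 and 6 of 13 for mitochondrially encoded genes, which under total read scaling were called lower (0 and 10, adjusted p = 0.03). They were 3 and 6 of 9 for Wnt targets, 13 and 8 of 24 for YAP and TAZ targets, and 9 and 16 of 30 for immediate early and MAPK feedback genes. In the prostanoid pathway, PTGES2, listed as a prostaglandin E synthase, fell to 0.5 of its vehicle level and SLCO2A1, a prostaglandin transporter, rose 2.37-fold.

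Markers of other cell types were also measured. Of 6 tested fibroblast and stellate cell markers 2 rose and 4 fell with TGF-β (adjusted p = 0.31), with LUM at 20.1 ± 1.3 FPKM in vehicle and 12.6 ± 0.589 FPKM with TGF-β. Of 6 endothelial markers 2 rose and 2 fell (adjusted p = 0.92), and of 5 leukocyte markers 3 rose and 0 fell (adjusted p = 0.14), among them CSF1R, a macrophage receptor gene, at 0.133 ± 0.0117 and 3.52 ± 0.0631 FPKM. Only 1 of 18 hepatocyte markers was tested, SERPINA1, which fell to 0.818 of its vehicle level.

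Among all tested genes, 3 genes of the chorionic gonadotropin beta chain rose most on the log2 scale. CGB5 (ENSG00000189052, chromosome 19 at 49043884 to 49045311) went from 0.376 ± 0.111 to 395 ± 5.65 FPKM, CGB8 from 1.65 ± 0.114 to 186 ± 15.5 FPKM, and CGB3 from 0.06 ± 0.0595 to 57.1 ± 3.65 FPKM. These genes are near-identical copies, so how the reads divide among them is uncertain. Their summed reads with LHB rose from 2.98 to 609 per M, scaled by the library totals inside the deposited FPKM.

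**Figure D2:**
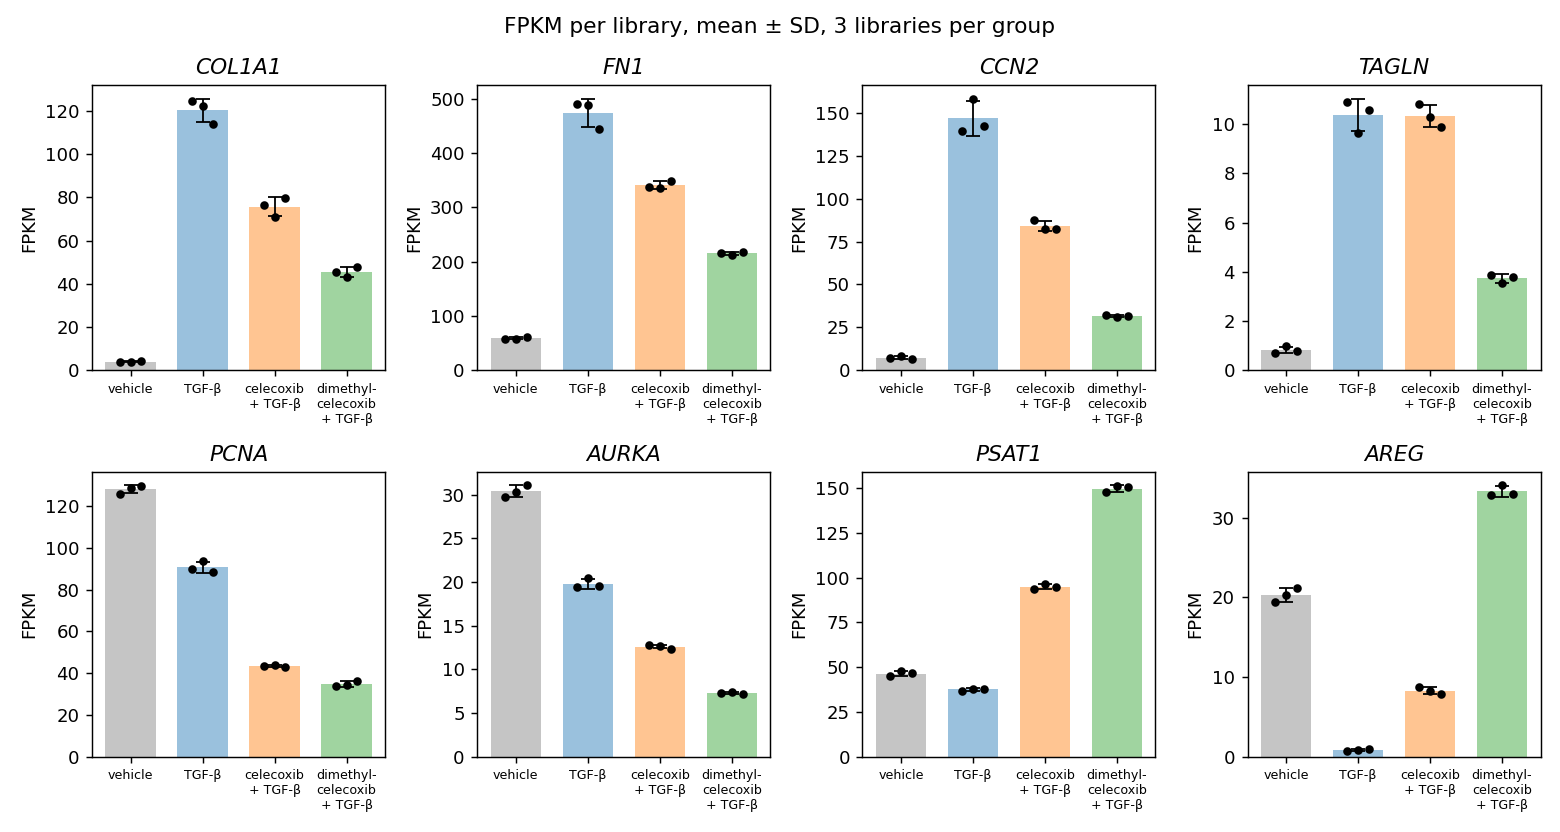
Mean FPKM with SD and the 3 libraries of each group for COL1A1, FN1, CCN2, TAGLN, PCNA, AURKA, PSAT1 and AREG. COL1A1 rises from 3.81 to 120.5 FPKM with TGF-β and lies at 75.7 with celecoxib and 45.4 with the analog, while TAGLN lies at 10.4, 10.3 and 3.73 FPKM in the same 3 groups.

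Celecoxib with TGF-β against TGF-β alone asks what the drug changes in cells given TGF-β. No group received a compound without TGF-β, so an action on the TGF-β response cannot be told apart from one independent of it. Proliferation genes fell further and genes of the ATF4 stress response rose, while no matrix list was called. E2F1 fell from 31.6 ± 0.831 to 9.74 ± 0.394 FPKM (SD, n = 3; log2 change -1.60, SE 0.04, limma adjusted p = 1e-09) and PCNA from 90.7 ± 2.56 to 43.5 ± 0.415 FPKM. COL1A1 fell to 75.7 ± 4.45 FPKM, 0.628 of the level with TGF-β alone, and FN1 fell to 341 ± 7.57 FPKM, 0.717 of it. ODC1, the first enzyme of polyamine synthesis, rose 3.97-fold to 211 ± 5.17 FPKM, and AREG rose 9.60-fold to 8.29 ± 0.438 FPKM.

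In all, 2354 genes rose and 1982 fell (29.2% of 14870), of which 57 and 81 changed by at least 1 on the log2 scale. With total read scaling 1544 rose, and the share of called genes that rose went from 54.3% to 36.6%.

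All 50 tested genes of DNA replication and G1/S fell (50 adjusted over the list alone; adjusted p = 6.6e-40; adjusted p = 3.1e-05 with an estimated correlation). RRM2, the small subunit of ribonucleotide reductase, fell to 0.326 of the level with TGF-β alone, and MCM4, a subunit of the replicative helicase, to 0.413 of it. Of 60 mitosis and G2/M genes 56 fell and 0 rose (56 and 0 adjusted over the list alone; adjusted p = 2.3e-30; adjusted p = 0.0099 with an estimated correlation), with MKI67 at 3.08 ± 0.202 FPKM and AURKA at 12.6 ± 0.204 FPKM. The list of CDK inhibitors and D cyclins was lower, 1 up and 7 down of 13 (2 and 7 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.082 with an estimated correlation). Its members went apart: CDKN2C, a CDK4 and CDK6 inhibitor, fell to 0.411 of the level with TGF-β alone, CCND3, a D cyclin, fell to 0.516 of it, and CDKN1A rose 1.41-fold. Targets of p53 were called higher, 12 up and 3 down of 27 (13 and 3 adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.068 with an estimated correlation), with 8 up and 4 down under total read scaling.

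ATF4 targets rose, 36 of 42 with 0 down (37 and 0 adjusted over the list alone; adjusted p = 2.7e-28; adjusted p = 0.002 with an estimated correlation). PSAT1, an enzyme of serine synthesis, rose 2.53-fold from 37.6 ± 0.748 to 95.1 ± 1.5 FPKM, TRIB3 rose 2.52-fold, and DDIT3, which encodes the stress factor CHOP, rose 2.12-fold. ER chaperones were called higher, 13 up and 2 down of 34 (15 and 2 adjusted over the list alone; adjusted p = 0.0055, and adjusted p = 0.22 with an estimated correlation), but 7 up and 5 down under total read scaling (adjusted p = 0.05 after rounding, still past the threshold). HSPA5 rose 1.16-fold. NRF2 targets were higher, 15 up and 4 down of 34 (15 and 4 adjusted over the list alone; adjusted p = 0.003, and adjusted p = 0.25 with an estimated correlation; 10 up and 5 down under total read scaling), with the ferritin gene FTH1 up 1.64-fold and HMOX1, heme oxygenase, up 1.69-fold. Aryl hydrocarbon receptor targets were called higher, 3 up and 0 down of 5 (3 and 0 adjusted over the list alone; adjusted p = 0.0064, and adjusted p = 0.076 with an estimated correlation), with CYP1B1 up 2.20-fold.

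Immediate early and MAPK feedback genes rose, 20 up and 1 down of 30 (23 and 1 adjusted over the list alone; adjusted p = 1.5e-11; adjusted p = 0.012 with an estimated correlation). DUSP5, a phosphatase of ERK, rose 2.89-fold and DUSP4 rose 2.27-fold. Hypoxia and glycolysis genes were called higher, 13 up and 4 down of 34 (15 and 6 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation), with 10 up and 7 down under total read scaling. HK2, a hexokinase, rose 3.01-fold and EGLN3, an oxygen sensor, fell to 0.576 of the level with TGF-β alone. Cholesterol synthesis and uptake was called lower, 2 up and 9 down of 26 (2 and 9 adjusted over the list alone; adjusted p = 0.03, adjusted p = 0.44 with an estimated correlation and adjusted p = 0.065 without TGF-β replicate 1), with the sterol synthesis gene LSS at 0.801 of the level with TGF-β alone.

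Integrins were called higher, 9 up and 2 down of 13 (9 and 2 adjusted over the list alone; adjusted p = 0.005, and adjusted p = 0.19 with an estimated correlation), with ITGA3 up 1.65-fold. Contractile genes were called lower, 3 up and 11 down of 22 (3 and 11 adjusted over the list alone; adjusted p = 0.048, and adjusted p = 0.24 with an estimated correlation). The call ended under TMM scaling, at a 1 CPM floor, with a pseudocount of 0.1 and in a fit of only 2 groups (adjusted p = 0.051, 0.066, 0.061 and 0.078). It also ended without 1 library, namely vehicle replicate 1, 2 or 3 (0.051, 0.057 and 0.06), TGF-β replicate 1 or 2 (0.087 and 0.055), celecoxib replicate 1 or 2 (0.054 and 0.062) and analog replicate 1 or 2 (0.051 and 0.052). CNN1, which encodes calponin, fell from 14.5 ± 0.715 to 6.73 ± 0.328 FPKM, and TAGLN was at 10.4 ± 0.661 and 10.3 ± 0.46 FPKM (log2 change -0.01, 95% interval -0.14 to 0.13). Of 18 collagens 3 rose and 8 fell (5 and 9 adjusted over the list alone; adjusted p = 0.16). Of 22 matrix glycoproteins 8 rose and 5 fell (8 and 7 adjusted over the list alone; adjusted p = 0.56; 7 and 7 under total read scaling). Of 30 remodelling enzymes 13 rose and 8 fell (13 and 8 adjusted over the list alone; adjusted p = 0.21), and of 21 immediate TGF-β targets 7 rose and 8 fell (8 and 9 adjusted over the list alone; adjusted p = 0.62). CCN2 fell to 84.1 ± 2.85 FPKM, 0.572 of the level with TGF-β alone. SMAD7, PMEPA1 and SPOCK1, also raised by TGF-β, were not lower with celecoxib. They were at 17.8, 332 and 104 FPKM, against 14.9, 326 and 90.3 with TGF-β alone. CCL2, a monocyte attractant, fell from 214 ± 12.9 to 77 ± 1.92 FPKM, and ELF3, an epithelial transcription factor gene, from 11.7 ± 0.245 to 2.81 ± 0.307 FPKM.

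The other tested lists were not called for celecoxib, among them epithelial junctions (5 rose and 8 fell of 22), cholangiocyte markers (4 and 5 of 15) and the prostanoid pathway (2 and 1 of 13, and 0 and 3 under total read scaling). Total read scaling added calls for ID genes, higher, and fatty acid synthesis, lower (adjusted p = 0.048 for each). Of the markers of other cells, 0 rose and 3 fell of 6 for fibroblasts, 0 and 2 of 6 for endothelial cells and 1 and 2 of 5 for leukocytes.

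The analog with TGF-β against TGF-β alone asks what a relative of celecoxib without COX-2 inhibition changes in cells given TGF-β. The lists of proliferation genes fell and that of ATF4 genes rose, as with celecoxib, and collagens and contractile genes were called lower (adjusted p = 0.33 and adjusted p = 0.054 with an estimated correlation). COL1A1 fell from 120.5 ± 5.46 to 45.4 ± 2.17 FPKM, 0.377 of the level with TGF-β alone (SD, n = 3; log2 change -1.39, SE 0.06, limma adjusted p = 6.8e-09), and FN1 fell to 215 ± 2.91 FPKM, 0.452 of it. TAGLN fell to 3.73 ± 0.172 FPKM and CCN2 to 31.6 ± 0.581 FPKM. PSAT1 rose 3.99-fold to 149.8 ± 1.82 FPKM, UPP1, which encodes uridine phosphorylase, rose 7.20-fold, and AREG rose 38.6-fold to 33.3 ± 0.671 FPKM.

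In all, 3308 genes rose and 3123 fell (43.2% of 14870), of which 123 and 278 changed by at least 1 on the log2 scale.

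All 50 tested DNA replication and G1/S genes fell (50 adjusted over the list alone; adjusted p = 2.3e-30; adjusted p = 4.9e-05 with an estimated correlation), with E2F1 at 8.34 ± 0.202 FPKM and PCNA at 34.7 ± 1.37 FPKM. Of 60 mitosis and G2/M genes 58 fell and 0 rose (58 and 0 adjusted over the list alone; adjusted p = 2.7e-32; adjusted p = 0.009 with an estimated correlation). MKI67 fell to 1.64 ± 0.104 FPKM, 0.23 of the level with TGF-β alone, and KIF20A, a mitotic kinesin, to 0.271 of it. The list of CDK inhibitors and D cyclins was called lower, 4 up and 9 down of 13 (4 and 9 adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.12 with an estimated correlation), with CDKN2C down to 0.138 of the level with TGF-β alone and CDKN1A up 1.72-fold.

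Collagens were called lower, 3 up and 11 down of 18 (3 and 11 adjusted over the list alone; adjusted p = 0.0063, and adjusted p = 0.33 with an estimated correlation), with COL4A1 at 0.563 of the level with TGF-β alone. Matrix glycoproteins (8 rose and 10 fell of 22, adjusted p = 0.22) and remodelling enzymes (11 rose and 14 fell of 30, adjusted p = 0.42) were not called. Contractile genes were called lower, 3 up and 14 down of 22 (3 and 14 adjusted over the list alone; adjusted p = 8.9e-05, and adjusted p = 0.054 with an estimated correlation), with CNN1 at 1.60 ± 0.302 FPKM. Mesenchymal transition genes were called lower, 1 up and 6 down of 10 (1 and 6 adjusted over the list alone; adjusted p = 0.0062, and adjusted p = 0.068 with an estimated correlation), with SPARC, a matricellular protein gene, at 0.241 of the level with TGF-β alone. The immediate TGF-β targets were not called (4 rose and 11 fell of 21, adjusted p = 0.059), and BAMBI, a decoy receptor gene, fell to 0.357 of the level with TGF-β alone. SMAD7 was at 15.3 FPKM with the analog, PMEPA1 at 331 and SPOCK1 at 111, against 14.9, 326 and 90.3 with TGF-β alone. Integrins were called higher, 8 up and 2 down of 13 (8 and 3 adjusted over the list alone; adjusted p = 0.0098, and adjusted p = 0.21 with an estimated correlation).

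ATF4 targets rose, 39 of 42 with 0 down (39 and 0 adjusted over the list alone; adjusted p = 5.3e-26; adjusted p = 0.002 with an estimated correlation). SLC7A11, a cystine transporter, rose 5.98-fold and DDIT3 rose 3.49-fold. NRF2 targets were called higher, 21 up and 4 down of 34 (22 and 4 adjusted over the list alone; adjusted p = 4.4e-05, and adjusted p = 0.14 with an estimated correlation), with HMOX1 up 4.22-fold. Immediate early and MAPK feedback genes rose, 21 up and 2 down of 30 (21 and 2 adjusted over the list alone; adjusted p = 6.3e-09; adjusted p = 0.022 with an estimated correlation), with DUSP5 up 4.79-fold.

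Lipid synthesis genes were lower. Of 26 genes of cholesterol synthesis and uptake 2 rose and 17 fell (3 and 17 adjusted over the list alone; adjusted p = 8.2e-05, and adjusted p = 0.2 with an estimated correlation), with FDPS, a mevalonate pathway enzyme, at 0.673 of the level with TGF-β alone. Of 19 genes of fatty acid synthesis 2 rose and 11 fell (2 and 11 adjusted over the list alone; adjusted p = 0.0029, and adjusted p = 0.16 with an estimated correlation), with SREBF1, a transcription factor of lipid synthesis, at 0.398 of it and SCD, a fatty acid desaturase, at 0.522 of it. Interferon-stimulated genes were called lower, 3 up and 16 down of 30 (4 and 16 adjusted over the list alone; adjusted p = 0.0073, and adjusted p = 0.057 with an estimated correlation). CCL2 fell to 30.5 ± 0.577 FPKM and TNF, an inflammatory cytokine, to 0.179 of the level with TGF-β alone.

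Junction genes (8 rose and 10 fell of 22), cholangiocyte markers (4 and 4 of 15), the prostanoid pathway (4 and 3 of 13) and the markers of fibroblasts (0 and 3 of 6), endothelial cells (1 and 1 of 6) and leukocytes (1 and 2 of 5) were among the lists not called for the analog. LUM was at 6.56 ± 0.577 FPKM and CSF1R at 2.44 ± 0.184 FPKM in this group.

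**Figure D3:**
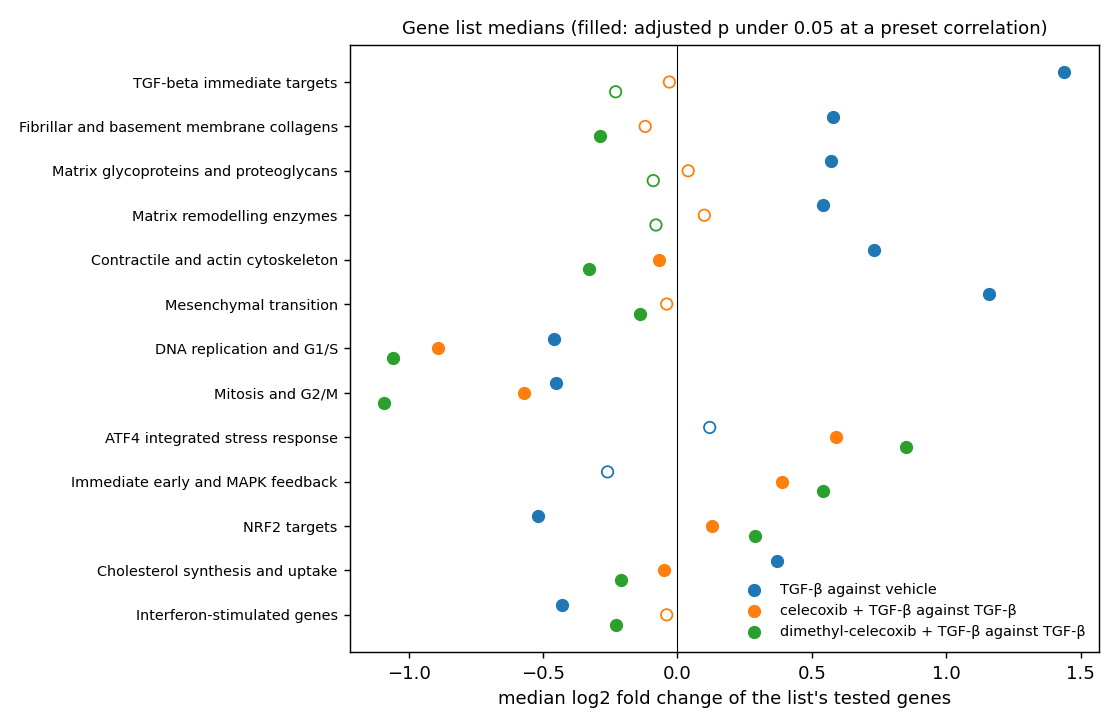
Median log2 change of 13 gene lists in the comparisons of TGF-β with vehicle and of each compound with TGF-β alone, with filled points for camera adjusted p under 0.05. The DNA replication list has medians of -0.46, -0.89 and -1.06, and the ATF4 list 0.12, 0.59 and 0.85, for TGF-β, celecoxib and the analog.

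Celecoxib was compared with the analog directly, at the same 10 µM dose, the same times and the same TGF-β dose. Mitotic genes were higher with celecoxib than with the analog, and ATF4 targets were lower. The 3 matrix lists were called higher as well, but these calls were lost with an estimated correlation (adjusted p = 0.2 for collagens, adjusted p = 0.24 for glycoproteins and adjusted p = 0.3 for remodelling enzymes). AURKA was at 12.6 ± 0.204 FPKM with celecoxib and 7.29 ± 0.0929 with the analog (SD, n = 3; log2 difference 0.71, SE 0.03, limma adjusted p = 1.7e-07). COL1A1 differed by 0.72 (95% interval 0.60 to 0.85), TAGLN by 1.26 (1.13 to 1.40) and LOX by 1.51 (1.34 to 1.67). PSAT1 was lower with celecoxib by a log2 difference of -0.65 (-0.72 to -0.59) and UPP1 by -1.38 (-1.46 to -1.30).

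In all, 1939 genes were higher with celecoxib and 1528 higher with the analog (23.3% of 14870), of which 45 and 13 differed by at least 1 on the log2 scale. With total read scaling the share of called genes higher with celecoxib went from 55.9% to 45.2%.

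Some genes differed little between the compounds, with a narrow interval. PMEPA1 was at 332 ± 6.36 and 331 ± 5.77 FPKM (log2 difference 0.01, 95% interval -0.08 to 0.09), and RGS4, a regulator of G protein signalling, at 17.6 ± 0.79 and 17.6 ± 1.0 FPKM (0.00, -0.12 to 0.13). MCM7, a helicase subunit gene, was at 15.4 ± 0.678 and 15.6 ± 0.232 FPKM (-0.02, -0.10 to 0.06). Over all genes, 8252 of 14870 (55.5%) had a 95% interval of the difference within 1.25-fold, and the median half-width of the interval was 0.16. These intervals are per gene, with no correction for the number of genes.

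In the mitosis and G2/M list 52 of 60 were higher and 0 lower (53 and 0 adjusted over the list alone; adjusted p = 7.1e-30; adjusted p = 0.0099 with an estimated correlation), with KIF20A 2.43-fold higher. In the DNA replication and G1/S list 23 of 50 were higher and 0 lower (29 and 0 adjusted over the list alone; adjusted p = 6.3e-09; adjusted p = 0.002 with an estimated correlation), with PCNA 1.25-fold higher.

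Among the fibrosis-related lists, contractile genes were higher with celecoxib, 11 against 1 of 22 (14 and 2 adjusted over the list alone; adjusted p = 3.8e-06; adjusted p = 0.027 with an estimated correlation), as were mesenchymal transition genes, 6 against 0 of 10 (7 and 0 adjusted over the list alone; adjusted p = 0.00021; adjusted p = 0.024 with an estimated correlation), with VIM 1.33-fold higher. Collagens were called higher, 10 against 0 of 18 (10 and 0 adjusted over the list alone; adjusted p = 9e-05, and adjusted p = 0.2 with an estimated correlation), and so were matrix glycoproteins, 11 against 2 of 22 (11 and 2 adjusted over the list alone; adjusted p = 8.9e-05, and adjusted p = 0.24 with an estimated correlation). Remodelling enzymes were called higher, 13 against 6 of 30 (16 and 7 adjusted over the list alone; adjusted p = 0.0032, and adjusted p = 0.3 with an estimated correlation), with MMP9, a gelatinase, at 15.6 ± 0.183 and 4.37 ± 0.268 FPKM and MMP1, a collagenase, at 7.60 ± 0.707 and 11.4 ± 0.9 FPKM. Immediate TGF-β targets were called higher, 11 against 3 of 21 (11 and 3 adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.054 with an estimated correlation), ID genes 2 against 0 of 3 (3 and 0 adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.22 with an estimated correlation), and YAP and TAZ targets 11 against 2 of 24 (12 and 3 adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.14 with an estimated correlation).

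ATF4 targets were lower with celecoxib, 33 of 42 with 0 higher (34 and 1 adjusted over the list alone; adjusted p = 1.3e-19; adjusted p = 0.004 with an estimated correlation), with SLC7A11 at 4.88 ± 0.247 and 10.8 ± 1.06 FPKM. NRF2 targets were called lower, 13 against 3 higher of 34 (17 and 4 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.12 with an estimated correlation), with HMOX1 at 13 ± 0.787 and 32.4 ± 1.49 FPKM. Immediate early and MAPK feedback genes were called lower, 14 against 5 higher of 30 (16 and 6 adjusted over the list alone; adjusted p = 0.00016, and adjusted p = 0.091 with an estimated correlation), with DUSP5 at 27.2 ± 1.66 and 45.2 ± 1.41 FPKM.

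Lipid and inflammatory lists were higher with celecoxib. Cholesterol genes were called higher, 13 against 0 of 26 (13 and 1 adjusted over the list alone; adjusted p = 7.7e-05, and adjusted p = 0.2 with an estimated correlation), and fatty acid synthesis genes 11 against 1 of 19 (12 and 1 adjusted over the list alone; adjusted p = 0.00016, and adjusted p = 0.087 with an estimated correlation), with SCD 1.54-fold higher. NF-kB and inflammatory cytokine genes were called higher, 16 against 4 of 33 (17 and 5 adjusted over the list alone; adjusted p = 0.003, and adjusted p = 0.24 with an estimated correlation): CCL2 was 2.53-fold higher with celecoxib and IL1B was at 80.3 ± 3.66 against 130.5 ± 6.47 FPKM. Interferon-stimulated genes were higher, 11 against 2 of 30 (13 and 2 adjusted over the list alone; adjusted p = 0.0022; adjusted p = 0.033 with an estimated correlation).

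Lists not called between the compounds included integrins (3 higher and 4 lower of 13), junction genes (6 and 5 of 22), cholangiocyte markers (4 and 3 of 15, but 3 and 5 under TMM or total read scaling), p53 targets (8 and 3 of 27) and ER chaperones (10 and 8 of 34, but 8 and 9 under total read scaling). For markers of other cells the counts were 2 and 0 of 6 for fibroblasts, 2 and 0 of 6 for endothelial cells and 1 and 1 of 5 for leukocytes. Over the 4 comparisons 57 of 144 list tests were called, and 19 of these held with an estimated correlation. The median, mean and test of a list differed in sign in 16 tests, all outside the 57. In 27 cases no member of a list passed in a given direction with limma, and at an unadjusted p under 0.05 at most 1 member did.

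The changes with the 2 compounds were set side by side, and both used the same TGF-β libraries. Of the genes called for both, 3480 changed in the same direction and 76 in opposite directions. The second count was 45 without TGF-β replicate 1, 45 without celecoxib replicate 1, 45 when each fit held only 2 groups and 48 with no expression floor. Independent lists of these sizes would share 940 and 935. In 100 simulations the libraries of all groups were drawn from the same mean for each gene, and the simulated TGF-β group was shared. Both counts were 0 there, which follows from a setting in which no gene changed. Among the genes changed alike, 1826 rose (524 for independent lists) and 1654 fell (416 for independent lists). The correlation of log2 changes across genes was 0.79, against 0.5 in these simulations of noise alone. The covariance was 0.086 against 0.01, a difference of 0.075. Genes are not independent replicates, and with 3 TGF-β libraries the controls could not be split, so part of the excess may come from the shared libraries.

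Of the 3480 genes changed alike, 1375 differed between the compounds in the direct test, 1294 of them with the larger change for the analog, like COL1A1, AURKA and PSAT1, and 81 with the larger change for celecoxib, like ELF3 and DHRS3, a retinal reductase gene (log2 difference -1.37, 95% interval -1.48 to -1.25). The other 2105 did not pass the direct test, and 2108 of the 3480 had an interval within 1.25-fold. The median ratio of the analog's change to celecoxib's was 1.35. Of 780 genes called for celecoxib alone, 328 differed in the direct test, and of 2875 called for the analog alone, 1352 did.

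**Figure D4:**
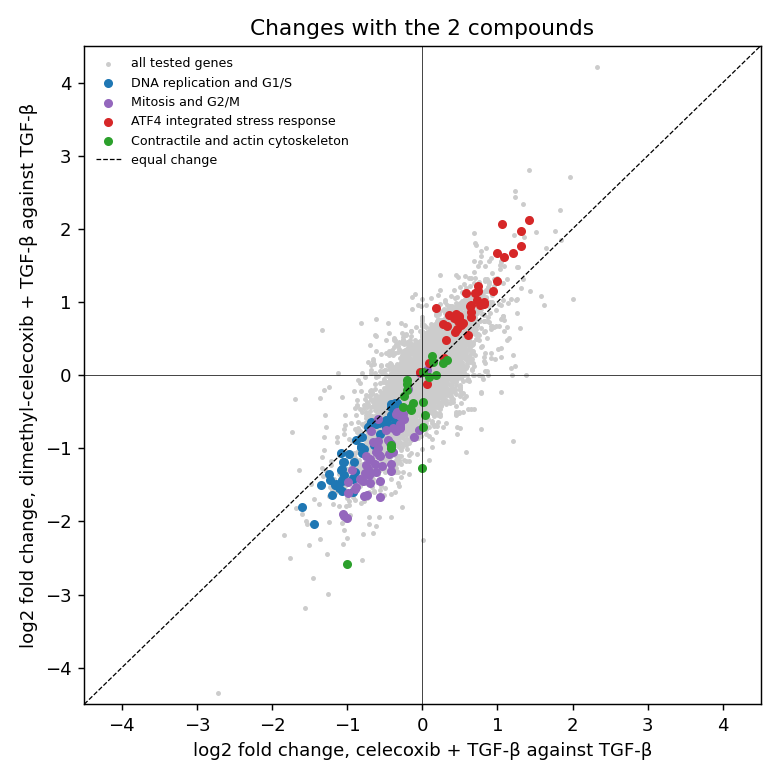
Log2 change of each tested gene with celecoxib (x axis) and with the analog (y axis), both against TGF-β alone, with 4 lists coloured and a dashed line of equal change. Of the genes called for both compounds, 3480 changed in the same direction and 76 in opposite directions.

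The compounds were also set against the TGF-β response itself. Without a group given a compound alone, a move back or further can also be an effect independent of TGF-β. Of the genes changed by TGF-β, 1570 changed the opposite way with celecoxib, like COL1A1, FN1 and AREG, and are counted here as moved back. Another 1584, like PCNA and E2F1, changed the same way and are counted as moved further. Independent lists would share 1138 and 1137. A gene counted as moved back need not end nearer to its vehicle level. PSAT1, for example, was at 46.4 FPKM in vehicle, 37.6 with TGF-β, 95.1 with celecoxib and 149.8 with the analog. How many genes passed their vehicle level was not counted. The analog moved 2599 back and 1817 further, against 1687 and 1686 for independent lists. The simulations gave 0 on average in all 4 cases, with a highest value of 1 for genes moved back by celecoxib and 0 for the other 3. No simulated gene responded to TGF-β, so these counts follow from the setting and are no control for a real response. The correlation of log2 changes with those of TGF-β was -0.09 for celecoxib and -0.21 for the analog. In the simulations, where no gene changed, shared libraries alone gave -0.5, which is no reference for correlations that hold real changes. The covariances were -0.014 and -0.044 against -0.01 in the simulations, differences of -0.004 and -0.034.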

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

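Of the tests in this part, those of the library scaling were chosen only after the result was seen; the tests of GC content, of 1 common factor and of the splits of the libraries were fixed before the result each one measures was seen.

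A set of 76 genes drew attention because celecoxib and the analog moved them in opposite directions, each past the threshold. Of these, 58 were higher with celecoxib and lower with the analog, and 18 went the other way; that all 76 also differed in the direct test of the compounds follows from how they were chosen. The 8 with the largest difference among those with mean log2 CPM of at least 3 follow as FPKM with TGF-β alone, with celecoxib and with the analog, each with the log2 difference of celecoxib minus the analog. MMP9, a gelatinase, was at 10.2, 15.6 and 4.37 FPKM (1.63). ID3, an inhibitor of differentiation factors, was at 35.4, 50.2 and 24.4 FPKM (1.01), PSG5, a pregnancy-specific glycoprotein gene, at 3.67, 5.4 and 2.19 FPKM (0.999), and GALNT12, a glycosyltransferase gene, at 19.8, 12.6 and 25.1 FPKM (-0.94). AGR2, a secretory protein gene, was at 2.65, 1.84 and 4.07 FPKM (-0.84), and SLC7A2, a cationic amino acid transporter, at 1.02, 1.87 and 0.656 FPKM (0.79). SRGN, a proteoglycan gene, was at 14.2, 19.2 and 10.7 FPKM (0.79), and CD82, a tetraspanin, at 11.1, 15 and 8.64 FPKM (0.74).

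The mitosis list was higher and the ATF4 list lower with celecoxib than with the analog, with median log2 differences of 0.52 and -0.3. With the trend on GC content removed, whose Spearman correlation with the difference went from 0.21 to 0, the medians were 0.53 (quartiles 0.36 to 0.69) and -0.28 (quartiles -0.47 to -0.2), which argues against GC content as the whole cause. Scaling as the whole cause is argued against as well, since 1 factor per library moves all genes one way, and these lists went opposite ways. Under total read scaling the medians were 0.49 (quartiles 0.32 to 0.63) and -0.33 (quartiles -0.48 to -0.2). That setting moved the median of all genes only from 0.002 to -0.023, too little to be a test of its own. A response of the same kind at a larger size with the analog, by a common factor of 1.35, is argued against as the whole account by 15.1% of tested genes, 2252 in all, that departed from that factor. Among them were 35 of 60 mitosis genes, all lower with the analog than the factor gives. Of 50 DNA replication genes 8 departed, and of 42 ATF4 genes 12, beside 22.4% of the 3480 genes changed alike. Median departures were -0.31 for mitosis, 0.07 for replication and 0.08 for ATF4, so the replication and ATF4 medians lay near the factor. The test bears on proportion only and cannot tell a difference in kind from a larger response that is not proportional. A difference in kind stays a hypothesis, and a difference in uptake or effective dose was not tested.

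Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 7421 genes for TGF-β against vehicle, and the highest other split called 1. For celecoxib against TGF-β these counts were 3470 and 2, for the analog 5655 and 1, and between the compounds 2837 and 1. Lists called were 14 and at most 9 in another split for TGF-β, 11 and 7 for celecoxib, 13 and 8 for the analog, and 17 and 7 between the compounds.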

How the results depend on the processing

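TMM scaling, total read scaling, pseudocounts of 0.1 and 5 and removal of the GC trend were chosen after the data were seen. Leaving out 1 library in turn gave 3554 to 3896 genes higher and 3567 to 3937 lower with TGF-β, 1882 to 2364 and 1640 to 1982 with celecoxib, 2921 to 3298 and 2721 to 3103 with the analog, and 1470 to 1997 and 1093 to 1567 between the compounds. It gave 2949 to 3360 genes changed alike by both compounds, 1284 to 1580 moved back and 1235 to 1593 moved further by celecoxib, 2302 to 2567 and 1527 to 1813 by the analog, and 55 to 60 list calls. Genes changed in opposite directions were 45 to 78, with 45 without TGF-β replicate 1 and 45 without celecoxib replicate 1; they were also 48 with no expression floor and 45 in fits of only 2 groups, and the cause was not tested. A minimum log2 change of 1, which removes smaller changes by construction, left 588 and 314 genes for TGF-β, 57 and 81 for celecoxib, 123 and 278 for the analog, 45 and 13 between the compounds, and 104 changed alike. It left 31 moved back and 12 moved further by celecoxib, 108 and 18 by the analog, and 0 changed in opposite directions, where limma and limma-voom also gave 0 at an unadjusted p under 0.05. An adjusted p under 0.01, a stricter threshold by construction, left 1456 and 1272 for celecoxib, 1184 and 830 between the compounds, 2282 alike, 24 in opposite directions, and 941 and 969 moved back and further by celecoxib. Total read scaling left 1544 genes higher with celecoxib, which follows from its shift of the median of all genes from 0.009 to -0.037, and TMM scaling took the share higher between the compounds from 55.9% to 49.3%. Under total read scaling GALNT12, not called for TGF-β at a log2 change of 0.01, was lower at -0.13. This follows from the changed library factors, which also took the median of all genes from -0.005 to -0.112. Of 57 list calls 19 held with the correlation estimated in each list, so the other 38 rest on the preset correlation. Camera called 77 list tests with no expression floor, 20 of them gained, and 65 with limma-voom, 8 of them gained. Fry, which does not set a list against other genes, called 112. Apart from the 2 stricter thresholds and the list tests there were 22 settings, in which 71.8% to 98.9% of the genes called were called again in the same direction. Of the called genes named in the text, 90 of 93 kept call and direction in all 22 for TGF-β, 78 of 85 for celecoxib, 87 of 87 for the analog and 75 of 82 between the compounds. With the replicate number as a block the counts were 3834 and 3847 for TGF-β, 2260 and 1908 for celecoxib, 3262 and 3083 for the analog and 1868 and 1403 between the compounds, and 56 list tests were called. The list call that ended under the block was that of contractile genes with celecoxib (adjusted p = 0.059, against 0.011 to 0.087 over its other settings apart from the estimated correlation and fry). The 18 same-number correlations of deviations were -0.064 to 0.047, and 3 of 12 libraries correlated best with their own number, so the numbers were not taken as pairs. The alternative tool named in the plan for counts was not run, since the values are FPKM, and size factors in place of TMM were no separate setting, since the deposited values carry them. Genes under about 1 FPKM rest on few reads, and a missed threshold there does not show that a gene did not change.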

Other observations

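In this part the tests of paralog reads and of mitochondrial mRNAs, the gene families and MT-RNR2 were chosen only after the result was seen; for neighbouring genes and poly-A selection a bound on the median was fixed before and both medians met it, but the further demand that the upper quartile meet it too was added after both results were seen and left both tests undecided.

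ANGPTL4, a lipase inhibitor, went from 0.389 ± 0.179 FPKM in vehicle to 7.87 ± 0.655 with TGF-β, 21.4 ± 0.938 with celecoxib and 43.9 ± 3.5 with the analog (SD, n = 3), each step past the limma threshold. VEGFA, the angiogenic growth factor, was at 4.45, 22.6, 35.7 and 53.8 FPKM in the same order. GDF15, a stress-induced cytokine, fell from 119.8 to 18 FPKM with TGF-β and was at 43.8 FPKM with celecoxib and 107 FPKM with the analog. MMP7, a matrix metalloprotease, did not pass for TGF-β (5.38 and 5.79 FPKM) and fell to 1.35 with celecoxib and 0.657 with the analog. CRABP2, a retinoic acid binding protein, did not pass for TGF-β either (135 and 132 FPKM) except under total read scaling (log2 change -0.19) and fell to 45.7 and 25.6 FPKM.

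Gene families sharing a symbol stem were tested with camera, 421 families in 4 comparisons. Of 1684 tests 53 were called, and 0 with an estimated correlation, where 98 had an unadjusted p under 0.05. All 8 CXCL chemokine genes fell with TGF-β, with a median log2 change of -1.5 (adjusted p = 0.00015, and adjusted p = 0.6 with an estimated correlation; median -1.62 under total read scaling). Of 26 SEC genes, most of which encode parts of the secretory pathway, 19 rose with TGF-β and 0 fell (adjusted p = 0.00076, and adjusted p = 0.72 with an estimated correlation), and under total read scaling 17 rose and 2 fell. Of 22 SNHG genes, which host small nucleolar RNAs, 1 rose and 16 fell with TGF-β (adjusted p = 0.012), 12 rose and 0 fell with celecoxib (adjusted p = 0.0078) and 14 rose and 1 fell with the analog (adjusted p = 0.0031); each was adjusted p = 0.72 with an estimated correlation, and under total read scaling 10 rose and 1 fell with celecoxib.

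CGB5, CGB8 and CGB3, genes of the chorionic gonadotropin beta chain, had the largest rises with TGF-β among tested genes on the log2(FPKM + 1) scale. A shift of reads among near-identical copies would leave their sum as it was, but the summed reads per M of these genes and LHB rose 204-fold, from 2.98 to 609, which argues against it. Spread from a neighbouring active gene stays open, because the 20 other tested genes within 100 kb had a median log2 change of 0.61, under the bound of 1 fixed before, but quartiles of -0.09 and 1.46, the upper of which lies above it. Induction by TGF-β may be the source of the rise; the sum was 389 with celecoxib and 192 with the analog, and no test of transcription was made here.

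MT-RNR2, the mitochondrial 16S rRNA gene, was at 5076 ± 184 FPKM with TGF-β, 6749 ± 295 with celecoxib and 7863 ± 201 with the analog (SD, n = 3; log2 changes 0.41 and 0.63), while MT-RNR1 did not pass (-0.10 and 0.14). More mitochondrial RNA of every kind is argued against by the 13 mitochondrial mRNAs, whose median log2 change with the analog was 0.04 with quartiles of -0.14 and 0.14. Weaker poly-A selection may still be the cause and cannot be told apart from the treatment: 362 small RNA genes had a median log2 change of 0.05, under the bound of 0.1 fixed before, but the quartiles were -0.22 and 0.36 and 356 of them rest on fewer than 10 reads per library.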
